A study of Mus musculus with 4 samples.

How the data were processed

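Mouse gingival mucosa was frozen in embedding medium and processed with the Visium Spatial Gene Expression kit, per the labels' protocols. Visium captures RNA from a tissue section on a hexagonal array of barcoded spots. A spot is a small region that can hold several cells. The submitters' processing notes name Cell Ranger, without a version, and the mouse genome build mm10. How spots were classed as tissue, by software or by hand, is not given in the sources used here. A different choice there would change the numbers of tissue spots, pieces and edge spots, but not the array size or image scale.

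For each of the 4 capture areas, 2 files were used. The deposited spot list holds, for each barcode, a tissue flag of 0 or 1, the array row and column, and the spot centre in pixels of the full-resolution image. These lists have no header, so their columns were read from their values and from the usual 10x layout. In all 4 lists the row and column numbers were both even or both odd in each spot. The pixel positions were linear in row and column to within 0.568 pixels. The deposited scale file gives the spot and fiducial diameters in pixels and the factors between the full-resolution and reduced images. No expression values were used, and no count, normalisation or sequencing depth enters any result. The 4 areas share 1 barcode layout but differ in tissue flags and pixel positions, so no area was a copy of another.

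Areas were grouped as GF or SPF and numbered from their titles. Each spot was given up to 6 neighbours, the adjoining spots of the hexagonal array. Adjoining tissue spots were joined into groups, and a group of at least 10 spots was called a piece. A tissue spot was called an edge spot when at least 1 neighbour on the array was off tissue, and an interior spot otherwise. Off-tissue spots were called enclosed when they could not reach the outermost spots of the array through other off-tissue spots. The length and width of a piece are the distances between its outermost spot centres along its principal axes in the image, divided by the median distance between neighbouring spots (the pitch). Regions were not given anatomical names, because nothing in the files identifies them.

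The number of tissue spots and the edge share were compared between groups by an exact two-sided permutation test over all 6 assignments of the 4 areas, which cannot give a p below 0.333. The other measures were described without a test. The labels do not say which SPF mouse gave which area, so no fit by animal was made. These tests, the minimum of 10 spots and the alternatives were fixed before the data were examined, except where stated. The alternatives were minimum piece sizes of 1, 5, 20 and 50 spots, joining across a gap of 1 spot, counting enclosed spots as tissue, using only pieces or only interior spots, other treatments of the array frame, grid in place of pixel coordinates, and leaving out each area in turn. No gene could be named under the rule set for naming genes, since no gene values were used.

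The arrangement of pieces was compared between areas by turning 1 area in steps of 10 degrees and shifting it until the overlap of its pieces with those of the other was highest. The overlap is the intersection over the union on a raster of 0.5 pitch. For each of the 6 pairs it was set against 100 random arrangements of the same pieces, each turned and placed at random and at least 1.5 pitches apart. Distances from small groups to the nearest piece, taken from 1 spot per group, were set against 10000 random placements off the pieces. All computations used Python 3.11.15 with numpy 2.4.6, and plots used matplotlib 3.10.9. The geometry functions were tested on 20 simulated arrays with known pieces, single spots, enclosed spots and spots on the array frame, and passed all 6 checks in each. For turns, the check was only that an array overlapped highly with its own turned copy, not that the angle was recovered. The simulated turns were multiples of the 10-degree step, so turns between steps were not checked.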

Results

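Gingival mucosa, the lining of the gum around the teeth, was placed on spatial transcriptomics capture areas from mice kept germ-free (GF, raised without microbes) and from mice kept in specific-pathogen-free housing (SPF, carrying a microbiota without listed pathogens). The series asks how gingival immune programmes vary by place and with the microbiota. The files analysed here record where the tissue lay on each array and the scale of its image. Gene expression was not analysed here, so no gene, cell type or depth of sequencing is reported. There were 4 capture areas, 2 from GF and 2 from SPF animals. According to the series design text, 4 samples came from 2 SPF mice and 3 samples from 1 GF mouse. Whether a sample in that text is a capture area or a piece of tissue was not stated, nor was the mouse behind each area. The GF areas come from 1 animal, and the SPF areas cannot be assigned to mice. Each mean ± SD, and each p that compares the groups, therefore describes capture areas and cannot be read as spread between animals. The p-values for the arrangement of pieces rank 1 pair of areas among random arrangements and measure neither spread.

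The tissue in all 4 areas took the form of a few separate, narrow strips on a mostly empty array. Each area carried 4992 spots in 78 rows of 64. Tissue covered 126 spots in GF area 1 and 128 spots in GF area 2, which is 2.52% and 2.56% of the array. It covered 139 spots in SPF area 1 and 144 spots in SPF area 2, or 2.78% and 2.88%. At the nominal Visium distance of 100 µm between spot centres, a value not given in the files, these numbers correspond to 1.09 and 1.11 mm2 of GF tissue and 1.20 and 1.25 mm2 of SPF tissue. Every tissue spot was counted there as a full cell of the hexagonal grid, also at edges and apart from the strips. These are therefore nominal areas and not measured ones. All spots of an array were classified, and neighbouring spots are not independent, so no counting interval is attached to these shares.

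**Figure D1:**
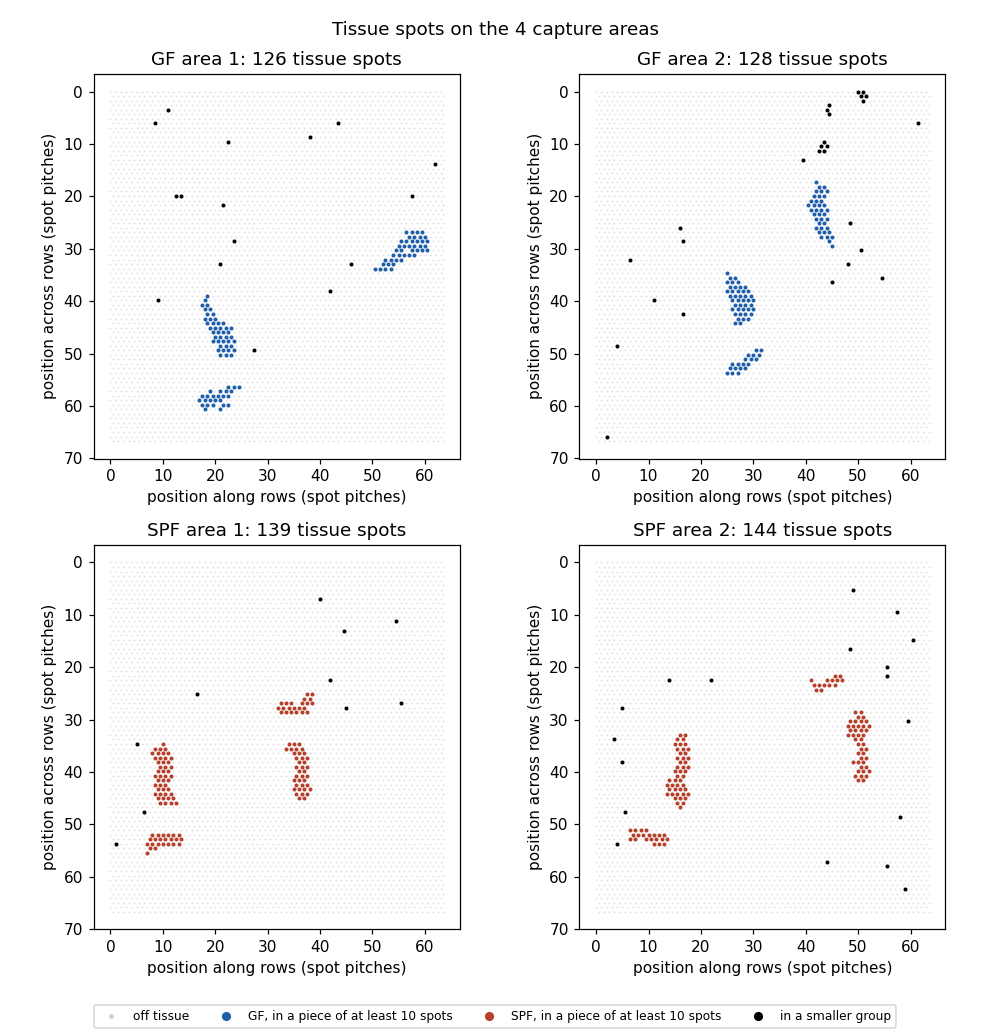
Positions of tissue spots on the 4 capture areas, in spot pitches along and across the array rows. Grey points are off-tissue spots, coloured points belong to pieces of at least 10 spots (blue GF, red SPF), and black points are tissue spots in smaller groups. GF areas hold 3 pieces each and SPF areas hold 4.

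The first comparison was of the amount of gingival tissue sampled in the SPF and GF groups, which sets how many spots any regional expression comparison can draw on. SPF areas held 141.5 ± 3.54 tissue spots (SD, n = 2) and GF areas held 127 ± 1.41 (SD, n = 2). The difference was 14.5 spots, and both SPF areas lay above both GF areas. The exact two-sided permutation test gave p = 0.333, the smallest value that this test can give with 2 areas against 2. The size of the difference depended on which spots were counted: it was 22 spots over pieces of at least 10 spots and 1.5 spots over interior spots, those with no off-tissue neighbour, where the groups overlapped.

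Tissue pieces were defined as groups of adjoining tissue spots with at least 10 members. Both GF areas held 3 pieces and both SPF areas held 4. With a minimum of 5 spots GF area 2 held 5 pieces. With a minimum of 20 spots it held 2, and SPF area 2 held 3. At the minimum of 10 spots the pieces of GF area 1 had 43, 42 and 25 spots, and those of GF area 2 had 43, 39 and 19. In SPF area 1 they had 46, 38, 23 and 22 spots, and in SPF area 2 they had 47, 44, 21 and 14. The median piece held 42 and 39 spots in the GF areas and 30.5 and 32.5 in the SPF areas. This order depended on the minimum size: the median of GF area 2 was 19 spots at a minimum of 5, and that of SPF area 2 was 44 spots at a minimum of 20, above both GF medians of 42 and 41. No test was made on piece sizes, because pieces of 1 area can come from 1 mouse.

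**Figure D2:**
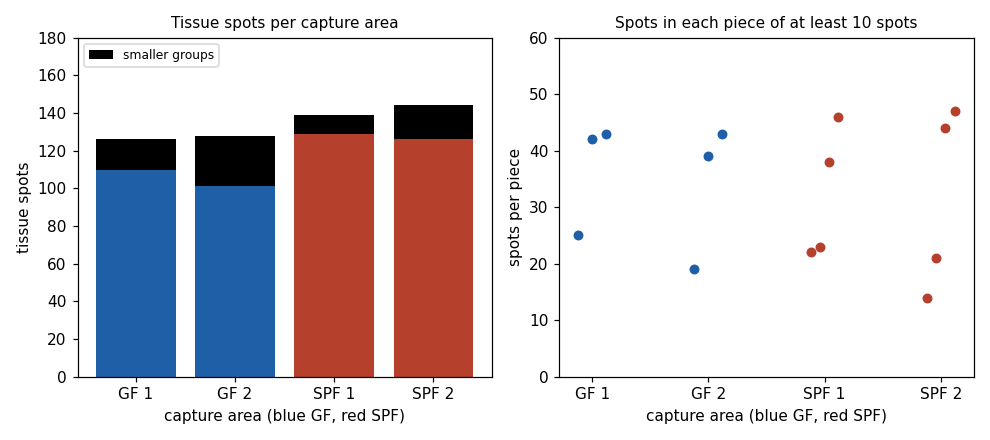
Left, tissue spots per capture area, split into spots in pieces of at least 10 spots (blue GF, red SPF) and in smaller groups (black). Right, the number of spots in each piece, 1 point per piece. The largest pieces held 43 spots in both GF areas and 46 and 47 spots in the SPF areas.

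The strips were longer than they were wide in every area. The ratio of the major to the minor axis (SD of spot positions along each) ranged from 2.09 to 3.85 over the 6 GF pieces and from 2.32 to 4.10 over the 8 SPF pieces. The median ratio per area averaged 3.09 ± 0.47 in GF (SD, n = 2) and 3.25 ± 0.53 in SPF (SD, n = 2), a difference smaller than the spread within either group. Between the outermost spot centres the GF pieces were 7.80 to 12.5 pitches long and 2.13 to 5.16 pitches wide. The SPF pieces were 5.77 to 13.9 pitches long and 2.20 to 4.11 pitches wide.

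Most tissue spots lay at a tissue edge. The share of tissue spots with at least 1 off-tissue neighbour was 81.0% in GF area 1 and 76.6% in GF area 2. It was 75.5% in SPF area 1 and 84.0% in SPF area 2. The group means were 78.8 ± 3.1% for GF and 79.8 ± 6.0% for SPF (SD, n = 2 each). The exact two-sided permutation test gave p = 1, and with 2 areas against 2 it cannot give a p below 0.333. The difference of 1.03 percentage points was smaller than the SD of either group. Its sign depended on single areas: the SPF share was lower by 1.17 percentage points without GF area 2, and was lower by 3.22 without SPF area 2. Within pieces alone the edge share was 78.2% and 70.3% in the GF areas and 73.6% and 81.7% in the SPF areas. There the SPF mean was higher by 3.46 percentage points. Interior spots numbered 24 and 30 in the GF areas and 34 and 23 in the SPF areas. Within single pieces the edge share ran from 58.1%, in the largest piece of GF area 2, to 100%, in the smallest piece of SPF area 2, where all 14 spots were at an edge.

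Some spots counted as tissue lay apart from the strips. Groups of fewer than 10 spots held 16 spots in GF area 1 and 27 spots in GF area 2, which is 12.7% and 21.1% of the tissue spots there. They held 10 spots in SPF area 1 and 18 spots in SPF area 2, or 7.19% and 12.5%. In the SPF areas all of these were single spots. GF area 1 had 14 single spots and a pair, and GF area 2 had 14 single spots and 3 groups of 5, 5 and 3 spots. The mean share was 16.9 ± 5.94% in GF and 9.85 ± 3.75% in SPF (SD, n = 2 each), and the values of GF area 1 and SPF area 2 were nearly equal.

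Off-tissue spots fully enclosed by tissue were rare. Strips this narrow leave little room for an enclosed spot, and gaps open to the side were not counted. The count therefore does not show that the strips were intact. A single off-tissue spot was enclosed by tissue, in GF area 1, and none was in the other 3 areas. No piece reached the outermost spots of the array in any area. In GF area 2, 2 tissue spots lay on that frame, both in a group of 5 spots. The size of that group is therefore a lower bound.

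The images of the 4 areas had almost the same scale. Neighbouring spot centres were 417.6 and 418.1 pixels apart in the GF images and 417.4 and 418.2 pixels apart in the SPF images. The spot diameter recorded with each image was 0.648 of that distance in all 4. These values show a like image scale only. Setting lengths in pitches side by side across areas rests instead on the arrays having the same physical pitch, which was taken as nominal.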

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

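Of the alternatives, 56 left the reported value in place, 19 moved it and 2 turned its sign. In place means the same direction for a group difference, within 1.5 times for a count, and within 1 SD between the areas of a group for other values. The 56 include 1 alternative chosen after seeing the data, the 2 largest pieces of each area. The SPF excess of tissue spots was 12 to 17 with 1 area left out, 14 with enclosed spots counted as tissue and 22 within pieces. Over interior spots it was 1.5, and its sign changes without GF area 1 or SPF area 1. The replicate number marks no known common origin. As a block it leaves the difference at 14.5 spots by construction, each group having 1 area per number. The exact sign-flip test gave p = 0.5, the smallest that 2 pairs can give. The edge share difference ranged from -3.22 to 5.27 percentage points with 1 area left out, and changed sign without GF area 2 or SPF area 2. It was 3.46 within pieces and 2.92 with the enclosed spot of GF area 1 counted as tissue. The exact tests cannot give a p below 0.333 here, so their p-values say nothing of stability.

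Piece counts followed the minimum size. At 1 spot they were 18 and 20 in GF and 14 and 22 in SPF, with a median size of 1 spot. At 5 spots GF area 2 had 5 pieces, with a median of 19 spots. At 20 spots the SPF area 2 median rose to 44 spots, with 3 pieces left, and GF area 2 kept 2. Both counts pass as in place, though GF area 1 also had 3. At 50 spots 0 pieces remained in any area, so that minimum gave no size or elongation. Joining across a gap of 1 spot changed no piece count. With a minimum of 3 spots, 0 enclosed spots remained in GF area 1. Within the outermost 2 rows or columns lay 1, 5 and 1 tissue spots in GF area 1, GF area 2 and SPF area 1. Elongation by grid coordinates and the pitch over tissue spots stayed within the spread between areas.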

Other observations

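All tests and splits in this part were chosen after the maps of tissue spots had been seen.

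The higher SPF number of spots in pieces lay mostly outside the largest pieces. The 2 largest pieces together held 85 and 82 spots in the GF areas and 84 and 91 spots in the SPF areas, a difference of 4 spots between the group means (exact two-sided permutation p = 0.667). The remaining pieces held 25 and 19 spots in the GF areas, where there was 1 such piece each. They held 45 and 35 spots in the SPF areas, where there were 2, a difference of 18 spots between the means. The larger of the 2 in the SPF areas held 23 and 21 spots, close to the GF pieces of 25 and 19. The excess outside the 2 largest pieces was therefore the 1 extra piece of each SPF area, of 22 and 14 spots. This split thus largely restates the number of pieces per area at the minimum of 10 spots.

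The number of pieces per area, 3 in GF and 4 in SPF, equals the number of samples that the series design text gives for each group. Among the minimums tried, this match held at 10 spots alone. At 5 spots GF area 2 had 5 pieces, and at 20 spots GF area 2 had 2 and SPF area 2 had 3. No group outside the pieces held more than 5 spots and no piece fewer than 14. Any minimum above 5 and up to 14 spots therefore gives the same counts. As a hypothesis, each pair of areas may hold sections of 1 tissue block, in which case the areas of a group would be repeat sections of the same strips. Best rigid overlap of the pieces was 31.3% between the GF areas and 23.0% between the SPF areas. These values lay at percentiles 91 and 85 of random arrangements of the same pieces, short of the percentile of 95 that the hypothesis called for but above the random median (one-sided permutation p = 0.0990 and 0.158, both 0.238 after Benjamini-Hochberg adjustment over 6 pairs). A layout shared by all areas was set against it, and the 4 pairs across groups had a median percentile of 82.5. GF area 1 lay at percentile 49 against SPF area 1 and at 99 against SPF area 2 (permutation p = 0.119 for the latter after the same adjustment), and GF area 2 lay at 88 and 77 against SPF areas 1 and 2. Neither explanation was excluded or borne out, so shared sections and a shared layout remain open. The random arrangements turned each piece by its own angle and spread the pieces over the whole array. Lying above their median is therefore weak support for either explanation. Without any turn or shift, the SPF areas shared 15 tissue spots, against 4.01 for independent placement of single spots, and the GF areas shared 0, against 3.23. Across groups, GF area 2 and SPF area 2 shared 10, against 3.69, and the other 3 pairs shared 1 to 3, so an excess was not particular to areas of 1 group. The tissue lies in clumps of 14 to 47 spots, so these chance values are no measure of significance. Separate mounting of tissue from different mice stays untested for SPF.

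The 60 small groups of tissue spots could be marks scattered over the array without relation to the strips. Their median distance to the nearest piece was 11.5 pitches, against a median of 13.9 and a central 95% range of 11.1 to 16.8 for random placement. Of the random placements, 5.25% gave a distance as short, so the groups were not shown to gather near the pieces. The median was below the random one in all 4 areas (13.2 against 15.1 pitches in GF area 1, 11.3 against 14.7 in GF area 2, 9.05 against 13.5 in SPF area 1 and 11.1 against 12.2 in SPF area 2), so a weak gathering stays open. Detached tissue was not separately tested. These groups made up 7.19% to 21.1% of the tissue spots of an area, and their origin is not settled by position alone.

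Groups of 3 to 9 spots occurred in GF area 2 alone, where 3 such groups held 13 spots. They lay between the top of the array and row 13, at 18, 13.2 and 6.08 pitches from the nearest piece.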
